A study of Mus musculus with 4 samples.

How the data were processed

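Gene expression was measured on Illumina mouse whole-genome bead arrays in 4 samples of cultured pre-B cells, 2 left untreated and 2 given an antibody against the immunoglobulin mu heavy chain. Per the labels' protocols, total RNA was amplified to biotin-labelled cRNA, and the submitters' processing notes name BeadStudio 3.1.1.0. The deposited non-normalized table holds 1 bead intensity per probe and array for 45281 probes, on a linear scale, with no background subtraction visible in the values. The authors' processed table holds intensity values on a linear scale after background subtraction, with values below 0 for 33.6% to 33.7% of probes and medians of 7.36, 7.36, 7.35 and 7.35 in untreated 1, untreated 2, anti-mu 1 and anti-mu 2. Set against the non-normalized table, the processed values of untreated 1 equalled the intensity minus a constant of 67.0, and those of the other arrays kept the rank order of the intensities (rank r of 1). The normalization method behind the processed values is not given in the sources used here. The non-normalized intensities were therefore the starting point, and the processed values served as an alternative.

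Groups were taken from the sample titles, which name untreated and anti-mu heavy chain samples with replicate numbers 1 and 2. The label field on activation gives the antibody for all 4 samples, the untreated ones included, and was not used for grouping. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values per probe measure only the spread between these samples, which may be technical. Nothing ties a replicate number in one group to the same number in the other, and no chip or scan batch was named in the columns used.

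The model, the thresholds, the gene lists and the rule for named genes were fixed before the data were examined. The planned background correction needed detection p-values, which the tables used here do not hold, and it was adapted before any test was run. The background centre of each array was the intensity at which the authors' processed value reached 0, and its SD came from the intensities below that centre. The centres were 67.0, 64.6, 64.7 and 62.1 intensity units in untreated 1, untreated 2, anti-mu 1 and anti-mu 2, with SDs of 7.57, 7.18, 7.37 and 6.58. A normal-exponential correction with this background and an offset of 16 was followed by quantile normalization and log2 transformation in limma 3.58.1 under R 4.3.3. A detection p was computed for each probe from the same background, as an estimate and not the scanner software's value. Probes with an estimated detection p under 0.01 on at least 2 of the 4 arrays were tested, which left 18226 probes. The number of arrays and the signal over background limit the precision, and the offset compresses fold changes of dim probes.

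Gene names came from the platform annotation supplied with the values, in which 34885 probes had 1 symbol, 18 had several and 10378 had none. Through gene identifiers, 34807 probes were matched to a current gene table, and 0 symbols changed. Of the tested probes 15685 had a single symbol, and these covered 9990 genes. A gene was represented by its tested probe with the highest mean normalized value. Of 267 genes with any probe past the threshold, 0 had such probes of opposite sign, and 43 were past it only through another probe than the representative one. Among 73 genes past the threshold with several tested probes, all probes had the same sign in 67, the exceptions being Acot1, Cbfa2t3, Dusp16, Nme7, Rassf4 and Tnfrsf13b.

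Anti-mu minus untreated was tested two-sided with lmFit and eBayes of limma, with 2 residual and 6.88 prior degrees of freedom, and with Benjamini-Hochberg adjustment over all tested probes at 0.05. Each log2 fold change is given with its moderated standard error and n = 2 per group. A gene detected on 0 arrays of a group has only a bound there, given as at least N-fold, where the dim group's mean takes, per array, the higher of the lowest detected signal and the probe's own value. Such a bound holds for the main processing and includes no sampling error. Other settings gave smaller changes for some of these genes. The 27 gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists. Camera asks whether a list's genes moved relative to the other genes tested, so a call alone is not a change from untreated. Alternatives were camera with an estimated correlation and fry (a rotation test of whether a list's genes, taken alone, move on balance in a single direction). At the preset, camera takes its degrees of freedom from the number of genes, so its p-values treat genes and not samples as the units. With an estimated correlation it uses at most the 2 residual degrees of freedom. No gene tested stood in several lists. Beside the count over all probes, the count with p adjusted over the list alone is given.

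The named genes were, among those past the threshold with both anti-mu arrays on the same side of both untreated arrays, the 15 with the largest rise and the 10 with the largest fall. To these were added up to 4 members of each list past the threshold, or the 2 with the smallest p where none passed, and 12 genes fixed by name, Egr1, Fos, Myc, Nr4a1, Cd69, Igll1, Vpreb1, Ighm, Rag1, Rag2, Il7r and Cd79a. The steps were tested on simulated data with the tested probes' own levels. Spreads were drawn at random from the fitted prior, with background noise added, and 50 probes were changed at each size. Few probes were changed, which makes the adjusted threshold stricter, so the recovery need not hold for the real data. Over 18226 probes, 0% of probes changed by 0.5 on the log2 scale were recovered, 12.0% of those changed by 1, 76.0% by 1.5 and 88.0% by 2, with 1 false call among 89. A simulated list of 20 genes shifted by 0.5 was called, and 1 of 100 unshifted lists had an unadjusted camera p under 0.05. The simulated noise was independent between genes. In the data the estimated correlations within lists ran from −0.18 (plasma cell markers) to 0.60 (G2 and M phase). The simulation therefore cannot give the rate of false calls for correlated lists.

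Alternatives were a normal-exponential correction on the signals alone with an offset of 50, no background correction, median scaling, the authors' processed values with and without an offset, no filter on dim probes, detection on all 4 arrays, the replicate number as a block, an intensity trend in the prior variance, each sample left out, the mean of a gene's probes, a 2-fold minimum, an adjusted p under 0.1, and the other list tests. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.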

Results

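Pre-B cells are the bone marrow B-cell precursors that carry the pre-B cell receptor (pre-BCR), built from the mu heavy chain, the surrogate light chain and the signalling chains Cd79a and Cd79b. The samples came from bone marrow of C57BL/6 mice aged 8 weeks. The cells had been cultured for 72 h with interleukin 7 over a limiting number of S17 cells, a bone marrow stromal line, and in 2 of the 4 samples the pre-BCR was then engaged for 3 h with goat F(ab')2 fragments against the mu heavy chain at 5 µg/ml. Estimated detection was similar across arrays, with 17968 and 18057 probes detected in untreated 1 and 2 and 17629 and 17804 in anti-mu 1 and 2, of 45281 probes on each. This similarity was partly given by the method and does not test array quality. The background centre left 33.6% to 33.7% of processed values below 0 on every array. Over tested probes the normalized values correlated at r = 0.993 between the untreated arrays, 0.991 between the anti-mu arrays and 0.981 to 0.988 between groups, a correlation across probes, which are not independent replicates. Transcripts of stromal cells were abundant on all 4 arrays, with a median normalized level of 10.67 (log2) over 27 stromal markers in the untreated samples.

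The comparison of anti-mu with untreated samples asked which transcripts differed after 3 h of pre-BCR engagement. Most of the genes that changed were lower after anti-mu, among them components of the pre-BCR and B-lineage transcription factors. Of 9990 genes tested, 224 changed, 193 of them lower and 31 higher. By representative probe the largest fall was that of Ralgps2, a Ral guanine nucleotide exchange factor, with a log2 fold change of −2.24 ± 0.21 (SE, n = 2 per group, adjusted p = 0.00311). The mean of its 4 tested probes was −1.34, a smaller fall than that of Zcchc18 (−1.91) in the same setting. The largest rise was that of Kprp at 1.42 ± 0.15 (adjusted p = 0.00412). Changes of at least 2-fold were found in 105 genes that fell and 6 that rose. In limma 1569 genes had an unadjusted p under 0.05, against 499.5 by chance. The probes past the threshold numbered 459, 404 lower and 55 higher. They included 138 probes without a gene name, 131 lower and 7 higher. Of the 87 named genes tested, the values of the groups did not overlap in 86, Slc2a3 being the exception, where chance gives 33.3%, and most of these genes were chosen for their change. Without anti-mu 1 0 genes passed (1167 at an unadjusted p under 0.05 in limma), against 338 without untreated 2, 247 without untreated 1 and 170 without anti-mu 2. These counts are not comparable: limma's prior degrees of freedom were infinite without untreated 1 or untreated 2, 5.53 without anti-mu 1 and 5.97 without anti-mu 2. Without anti-mu 1 the median log2 fold change was −0.93 against −1.02 over the 193 genes that fell. Over the 31 that rose it was 0.80 against 0.85, and all 224 kept their sign. The genes were chosen with the remaining arrays included, so this closeness was largely given by the choice and does not offset the lost calls. With the authors' processed values 6 genes passed, without a filter on dim probes 0 passed (2534 at an unadjusted p under 0.05), and with median scaling the split was 13 higher and 373 lower. Calls near the threshold went both ways: of 35 named genes that did not pass, 10 did in most other settings (Camp, Casp9, Cdc6, Cish, Dntt, Igll1, Mx1, Oasl1, Ppbp and Uhrf1), and of 52 that passed 1 (Retnlg) did not in most.

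**Figure D1:**
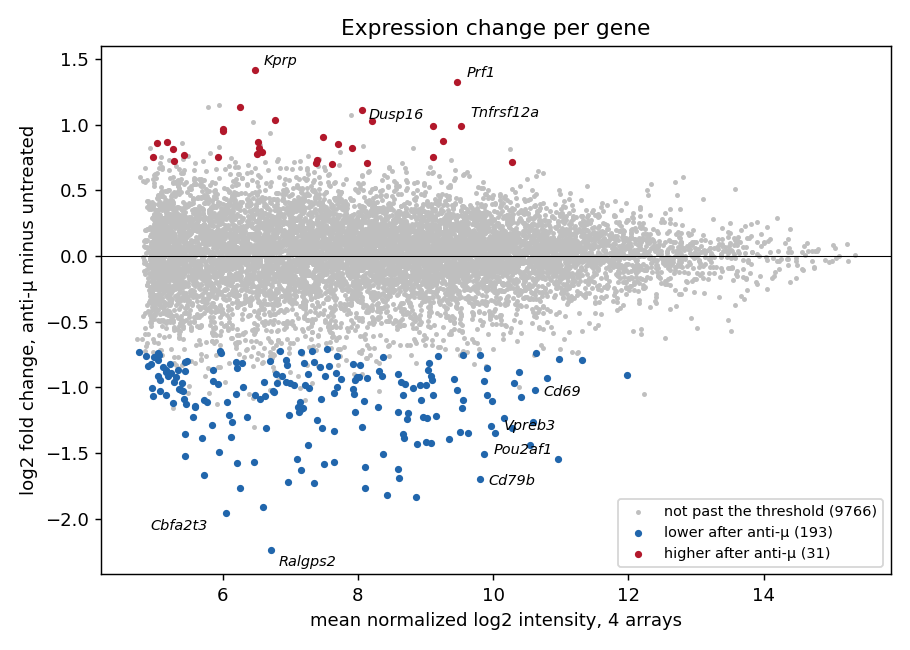
Log2 fold change (anti-mu minus untreated, vertical axis) against the mean normalized log2 intensity over the 4 arrays (horizontal axis) for 9990 genes, each point a gene. The 193 genes that fell (blue) outnumber the 31 that rose (red), and grey points did not pass an adjusted p of 0.05. With median scaling the split was 13 higher and 373 lower.

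The list of pre-BCR and proximal signalling components held the largest number of falls among the 27 lists. Of 23 measured members 13 fell, 0 rose and 10 did not pass, and adjusted over the list alone 20 fell. Cd79b, the signalling chain of the receptor, fell by 1.70 on the log2 scale (SE 0.18, adjusted p = 0.00412), from 10.65 ± 0.24 to 8.95 ± 0.22 (SD, n = 2 each). Vpreb3 had a log2 fold change of −1.35 ± 0.20, the Src-family kinase Blk −1.30 ± 0.19, and the inhibitory co-receptor Cd22 −1.29 ± 0.20. Cd22 was detected on only 1 of the 2 anti-mu arrays. The surrogate light chain gene Vpreb1 fell by 1.22 on the log2 scale (SE 0.23, adjusted p = 0.0297), while its partner Igll1, at −0.99 ± 0.22, did not pass (adjusted p = 0.0558) but did in 8 of 15 other settings, and Vpreb1 lost its call in 4. Ighm and Cd79a were not analysed here. The list median was −0.93 and camera gave an adjusted p of 6.9e-19, with an adjusted p of 0.385 with an estimated correlation. Beside it, the 27 stromal markers had a median of 0.11 and the 21 myeloid markers one of −0.32, with 0 members past the threshold. In 2 myeloid subsets chosen after the results were seen, 5 macrophage transcripts had a median of −0.56 and 5 neutrophil granule transcripts 0.82.

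Among transcription factors of the B lineage 7 of 24 fell, and among markers of immature and mature B cells 9 of 16. The other 17 transcription factors did not pass, with 9 of the list lower adjusted over the list alone. By representative probe the 4 with the largest changes were Bcl11a (−1.61 ± 0.18), the octamer coactivator Pou2af1 (−1.51 ± 0.17), the zinc finger factor Ikzf1 (−1.41 ± 0.16) and E2f2 (−1.23 ± 0.16), all as log2 fold change ± SE. With the mean of a gene's probes the order changed, with Pou2af1 at −1.51, E2f2 at −1.29, Bcl11a at −1.28 and Ikzf1 at −1.13. The median was −0.28, with a camera adjusted p of 1.4e-09 and an adjusted p of 0.385 with an estimated correlation. Of the immature and mature B cell markers 7 did not pass, with 14 of the list lower adjusted over the list alone. Ly6d had a log2 fold change of −1.69 ± 0.31, the inhibitory receptor Btla −1.23 ± 0.19, the tetraspanin Cd37 −1.16 ± 0.15 and the class II antigen presentation gene H2-Ab1 −1.09 ± 0.15. With the mean of their probes Ly6d had −1.53 and H2-Ab1 −0.88. The median was −0.82 (−0.66 with 3 members at their bound), with a camera adjusted p of 4.9e-13 and an adjusted p of 0.385 with an estimated correlation. Of 6 plasma cell markers 1 fell, also adjusted over the list alone, Mzb1 at −1.39 ± 0.16, and the list was not called (adjusted p = 0.612), its median of 0.02 and mean of −0.14 differing in sign. Of 8 genes of V(D)J recombination, which assembles antigen receptor genes, 0 passed and 2 were lower adjusted over the list alone. Rag1, the recombinase subunit, was at least 1.73-fold lower with anti-mu not detected (adjusted p = 0.0556), and Dntt, which adds nucleotides at the joins, had −1.13 ± 0.25 (adjusted p = 0.0536), and they passed in 6 of 14 and 8 of 15 other settings. The smallest log2 fold change of Rag1 over its 14 other settings was −0.57. Rag2 was detected on 0 arrays. The recombination list was not called (adjusted p = 0.0879), but was without untreated 1 (0.0232) and without untreated 2 (0.0233).

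**Figure D2:**
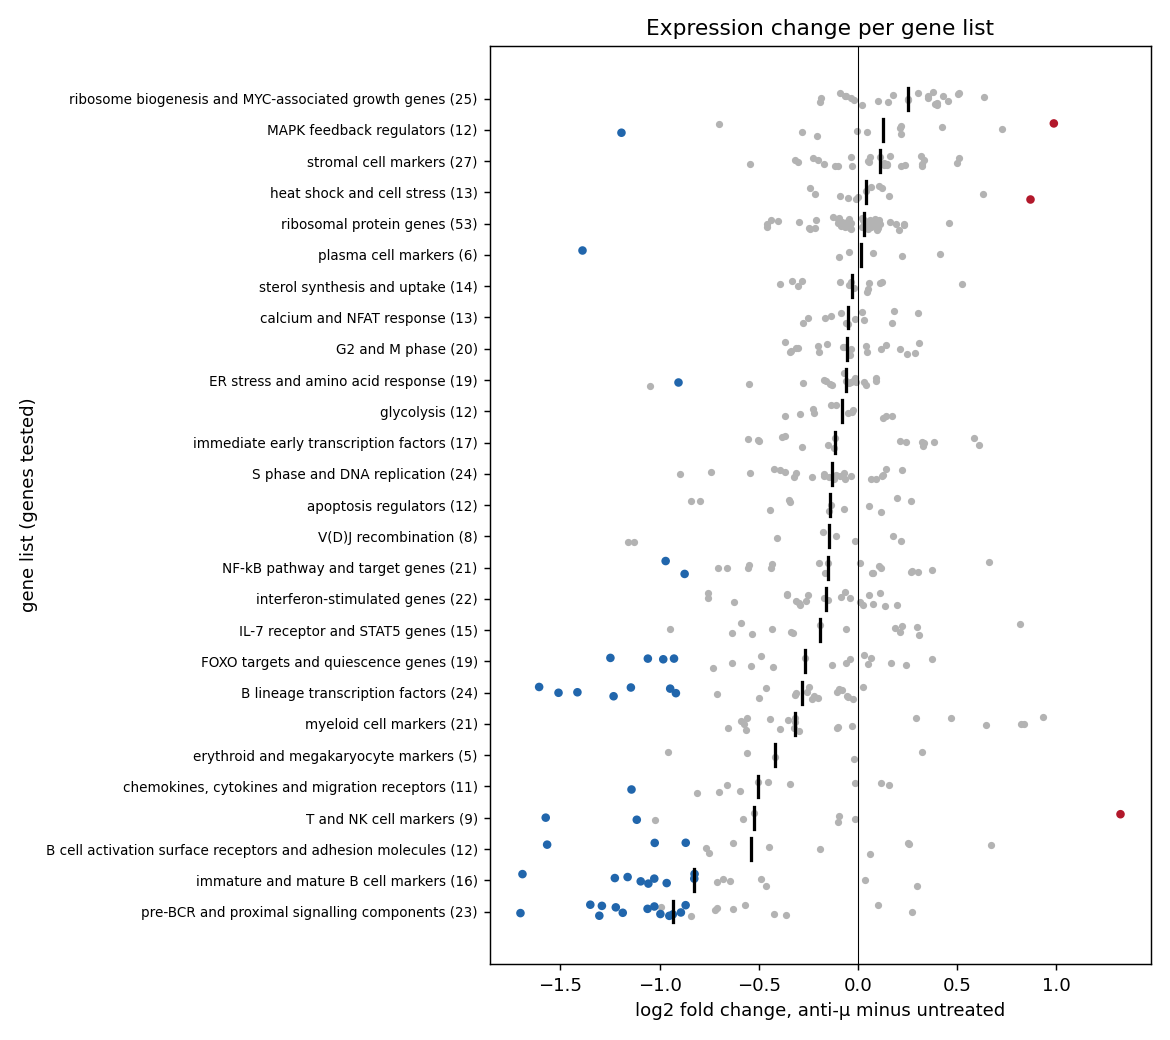
Log2 fold change (anti-mu minus untreated, horizontal axis) of each tested member of the 27 gene lists (vertical axis, number of genes tested in brackets). Each point is a gene, blue where it fell, red where it rose and grey where it did not pass, and the black bar is the list median, lowest at −0.93 for the pre-BCR list.

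Surface receptors of B-cell activation, chemokines with their receptors, and targets of FOXO factors held further falls. Of 12 activation receptors and adhesion molecules 3 fell and 9 did not pass, with 5 lower and 1 higher adjusted over the list alone. Tnfrsf13c, the receptor for the survival factor BAFF, fell by 1.57 on the log2 scale (SE 0.23), and the early activation antigen Cd69 fell by 1.02 (SE 0.18, adjusted p = 0.0226). Itgal was at least 1.45-fold lower (adjusted p = 0.0483), with anti-mu not detected, a call lost in 7 of 14 other settings, among them no background correction and the intensity trend, with a smallest log2 fold change of −0.40. The list median was −0.54 (−0.49 with 2 members at their bound), with a camera adjusted p of 0.00683, which became 0.0515 with median scaling, and an adjusted p of 0.503 with an estimated correlation. Of 11 chemokines, cytokines and migration receptors Cxcr4, the receptor for stromal Cxcl12, fell by 1.15 on the log2 scale (SE 0.18), and 10 did not pass, with 6 lower adjusted over the list alone. The median was −0.50 (−0.45 with 1 member at its bound), with a camera adjusted p of 0.000455 and an adjusted p of 0.385 with an estimated correlation. Of 19 FOXO targets and quiescence genes 4 fell and 15 did not pass, with 6 lower adjusted over the list alone. These were Ccng2 (−1.25 ± 0.21), Trp53inp1 (−1.06 ± 0.23), Tsc22d3 (−0.98 ± 0.19) and Klf2 (−0.93 ± 0.16), of which Trp53inp1 (−0.96) and Tsc22d3 (−0.65) did not pass with the mean of their probes. The median was −0.27, with a camera adjusted p of 0.00171 and an adjusted p of 0.503 with an estimated correlation.

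Immediate early genes, most of them for transcription factors, which many receptors induce within an hour, showed 0 calls among 17 measured, with 2 higher adjusted over the list alone. The antibody was given for 3 h only, so an earlier, transient change was not measured. Egr1 had a log2 fold change of −0.38 ± 0.17 (adjusted p = 0.318), Fos −0.56 ± 0.19 (0.195) and Myc 0.38 ± 0.19 (0.366). The smallest p-values of the list were those of Ier3, at 0.59 ± 0.15 (adjusted p = 0.0873), and Fosl2, at 0.61 ± 0.16 (0.0955). Nr4a1 was detected on 0 arrays. The list median was −0.11 and its mean 0.00, against −0.16 for the mean with median scaling, and it was not called (adjusted p = 0.993). Of 12 feedback regulators of MAP kinase signalling Dusp16, a phosphatase of stress-activated kinases, rose by 0.99 (SE 0.15, adjusted p = 0.0123), and the phosphatase Dusp2 fell by 1.19 on the log2 scale (SE 0.18, adjusted p = 0.0122). The probes of Dusp16 differed in sign, and their mean of 0.54 did not pass (adjusted p = 0.0849). A further 10 did not pass, and 2 were higher and 2 lower adjusted over the list alone (list adjusted p = 0.612). Of 21 genes of the NF-kB pathway Cd40 (−0.97 ± 0.20) and Nfkbid (−0.87 ± 0.18) fell and 19 did not pass, with 1 higher and 6 lower adjusted over the list alone, and both lost their call in 7 of 15 other settings, Cd40 with the mean of its probes (−0.73) among them. The list was not called (adjusted p = 0.0879), but was without untreated 1 (0.00882). Of 13 calcium and NFAT genes 0 passed, 0 also adjusted over the list alone (list adjusted p = 0.752), with Camk2d at −0.28 ± 0.15 and Ppp3ca, a calcineurin subunit, at 0.30 ± 0.15. Of 15 genes of the interleukin 7 receptor and STAT5 0 passed (list adjusted p = 0.219), with 1 higher and 3 lower adjusted over the list alone. The list was called where detection on all 4 arrays was required (mean −0.23, adjusted p = 0.0323), and its mean was 0.03 with the authors' processed values, against −0.13. Il7r had −0.33 ± 0.20 (adjusted p = 0.483), the STAT5 target Cish −0.95 ± 0.22 (0.0606), and the kinase Pim2 was at least 1.25-fold higher (0.0555) with untreated not detected.

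**Figure D3:**
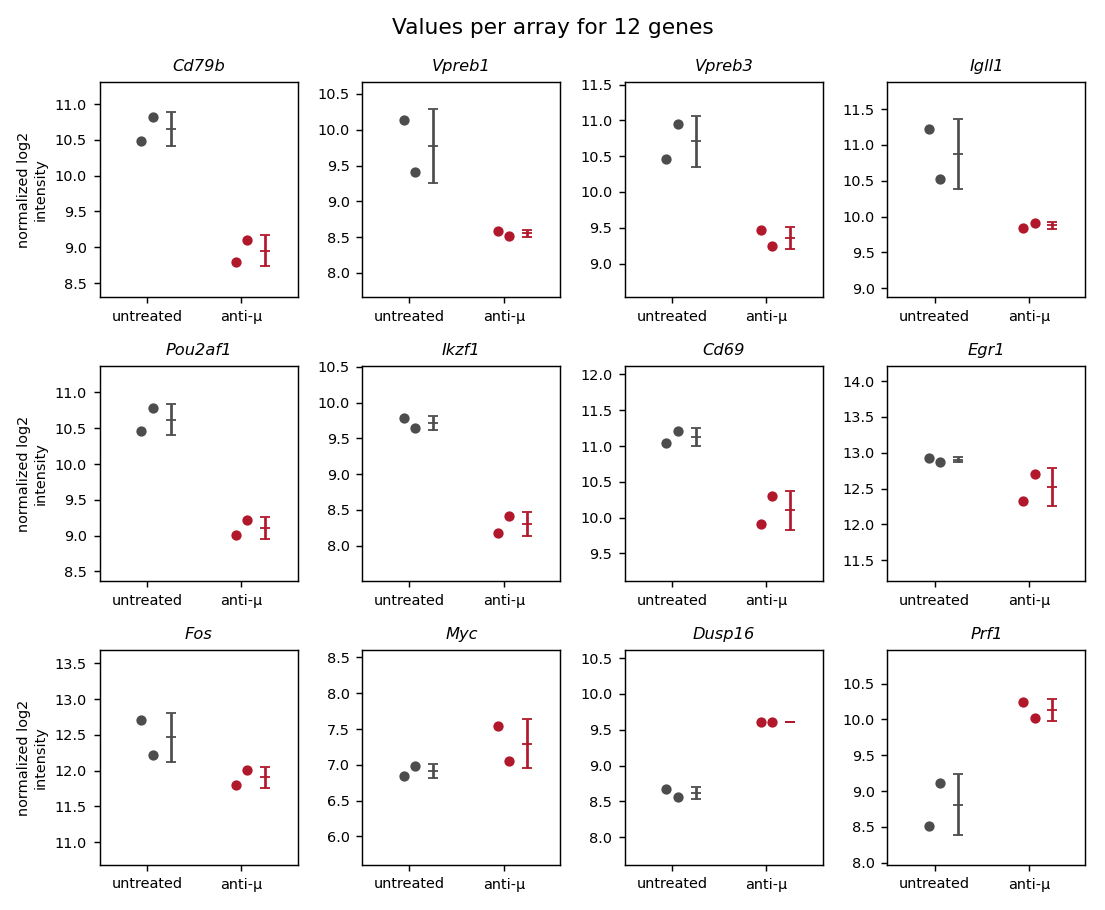
Normalized log2 intensity (vertical axis) of 12 genes on each array, untreated in grey and anti-mu in red. Points are single arrays and bars the mean ± SD of the 2 arrays, and every panel spans the same range of log2 units. Both anti-mu values of Cd79b lie below both untreated values, and those of Dusp16 and Prf1 above them.

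Genes of ribosome biogenesis and MYC-associated growth were called higher as a list by camera, with 0 of 25 members past the threshold and 0 adjusted over the list alone. The nucleolar proteins Nop56 (0.63 ± 0.15, adjusted p = 0.0709) and Nip7 (0.50 ± 0.16, adjusted p = 0.151) had the smallest p-values. The mean was 0.22, and 0.05 with median scaling. The list was still called there (camera adjusted p = 0.00189), where the median of all tested probes was −0.13. The median was 0.25, with a camera adjusted p of 0.00196, an adjusted p of 0.503 with an estimated correlation, 0.0992 without untreated 2 and 0.0533 without anti-mu 2. Of 24 genes of S phase 0 passed and 2 were lower adjusted over the list alone, with Cdc6, which loads the replicative helicase, at −0.90 ± 0.20 (adjusted p = 0.0524) and Uhrf1 at −0.74 ± 0.16 (0.0536). The S phase median was −0.13, with a camera adjusted p of 0.0153, an adjusted p of 0.707 with an estimated correlation, 0.511 without untreated 1 and 0.115 without anti-mu 2. Of 22 interferon-stimulated genes 0 passed and 3 were lower adjusted over the list alone, with Mx1 at −0.76 ± 0.18 and Oasl1 at −0.76 ± 0.17. The interferon median was −0.16, with a camera adjusted p of 0.0153, an adjusted p of 0.503 with an estimated correlation and 0.171 without untreated 2.

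The remaining lists of cell state were not called, and 0 members passed adjusted over the list alone except for 1 apoptosis, 1 endoplasmic reticulum stress and 1 heat shock gene. Among 20 genes of G2 and M phase 0 passed (list adjusted p = 0.612), with Nusap1 at −0.34 ± 0.15 and Cenpa at −0.34 ± 0.16. Glycolysis (12 genes, 0 passed, list adjusted p = 0.438) had Pgk1 at −0.29 ± 0.15 and Slc2a3 at −0.37 ± 0.24, the latter 0.01 without anti-mu 1. Sterol synthesis and uptake (14 genes, 0 passed, list adjusted p = 0.612) had Srebf2 at 0.52 ± 0.18 and Sc5d at −0.33 ± 0.15. Among 53 ribosomal protein genes 0 passed (list adjusted p = 0.752), with Rps15a at 0.46 ± 0.15 and Rpl22 at −0.46 ± 0.16, and a median of 0.03 against a mean of −0.02. Of 12 apoptosis regulators 0 passed, with Casp9 at −0.84 ± 0.19 and Bid at −0.45 ± 0.16. Casp9 passed in 10 of 15 other settings, and its log2 fold change over the 15 ran from −1.11 to −0.22, the latter with the mean of its probes, which did not pass. The apoptosis list was not called (adjusted p = 0.0879), but was without anti-mu 1 (0.00567). Of 19 genes of endoplasmic reticulum stress and the amino acid response Herpud1 fell by 0.91 on the log2 scale (SE 0.15) and 18 did not pass. That list was not called (adjusted p = 0.0901), but was without untreated 1 (0.00349), without anti-mu 1 (0.00567) and without a filter on dim probes (0.0464). Of 13 heat shock genes Hspa1b, an inducible Hsp70 chaperone, rose by 0.87 (SE 0.17, adjusted p = 0.0327), not past the threshold with median scaling, and the list was not called (adjusted p = 0.502).

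The 31 genes that rose included 3 members of the fixed lists, Prf1, Dusp16 and Hspa1b. After Kprp came Prf1, the pore-forming protein perforin, at 1.32 ± 0.21 (SE, adjusted p = 0.0164), the muscle caveolar protein gene Cavin4 at 1.13 ± 0.18, Retnlg at 1.11 ± 0.24, Hmga2-ps1 at 1.03 ± 0.17 and the zinc finger gene Zbtb2 at 1.03 ± 0.17. Tnfrsf12a, the receptor for the cytokine TWEAK, rose by 0.99 (SE 0.20), Cnksr3 by 0.97 (SE 0.16), Gprc5a by 0.95 (SE 0.15), the actin regulator Mical2 by 0.91 (SE 0.17) and Fam110c by 0.87 (SE 0.17). Epb41l5 was at least 1.51-fold and Jph2 at least 1.37-fold higher, with untreated not detected. Both calls were lost with a normal-exponential correction on the signals alone (0.38 and 0.39 on the log2 scale) and without background correction, and that of Jph2 also with the intensity trend. With median scaling 13 of the 31 stayed past the threshold, and Retnlg, Tnfrsf12a, Mical2, Fam110c and Hspa1b did not. Without anti-mu 1 Kprp (1.44), Prf1 (1.21) and Zbtb2 (0.93) kept log2 fold changes close to those above. Those of Cavin4 (0.93) and Tnfrsf12a (0.75) were smaller there, and that of Retnlg (1.44) was larger. Among the genes that fell most, after Ralgps2, were the transcriptional corepressor Cbfa2t3 (−1.96 ± 0.24), Zcchc18 (−1.91 ± 0.20), the kinase gene Sbk1 (−1.84 ± 0.25) and the B-cell Fc receptor-like gene Fcrla (−1.82 ± 0.24). They were followed by Gpr18 (−1.77 ± 0.22), the lymphocyte adaptor Sash3 (−1.77 ± 0.23), B3gnt5 (−1.73 ± 0.29) and the carboxypeptidase Cpm (−1.72 ± 0.24). Cbfa2t3 and Gpr18 were each detected on only 1 of the 2 anti-mu arrays. Their falls and ranks therefore rest partly on a value not above background. With the mean of their probes Cbfa2t3 (−0.84) and Retnlg (1.11, adjusted p = 0.0534) did not pass. In that setting Fcrla had −1.58 and Gprc5a 0.64 (adjusted p = 0.0498).

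Among markers of other cell types, 3 of the T and NK list passed the threshold, and 0 of the stromal, myeloid and erythroid lists did. Stromal markers (27 genes, 0 past the threshold and 0 adjusted over the list alone, list adjusted p = 0.438) had a median of 0.11 and a mean of 0.06, the mean being −0.10 with median scaling, which moved the median of all tested probes to −0.13. Ccn2 had a log2 fold change of 0.50 ± 0.19 and Igfbp4 −0.55 ± 0.16. Myeloid markers (21 genes, 0 past the threshold, list adjusted p = 0.117, or 0.0409 without a filter on dim probes) had 4 members higher and 5 lower adjusted over the list alone, with the neutrophil granule gene Camp at 0.93 ± 0.21 (adjusted p = 0.0555) and the macrophage complement gene C1qc at −0.66 ± 0.17 (0.0888). Of 9 T and NK cell markers Cd2 (−1.57 ± 0.31) and Thy1 (−1.11 ± 0.21) fell and Prf1 rose, with 1 higher and 5 lower adjusted over the list alone. In mice Cd2 is also expressed on B-lineage cells. The T and NK list had a median of −0.52 and a camera adjusted p of 0.0153, with an adjusted p of 0.503 with an estimated correlation, 0.122 without anti-mu 2 and 0.0763 with median scaling. Erythroid and megakaryocyte markers (5 genes, 0 past the threshold, 3 lower adjusted over the list alone) had a median of −0.42 (−0.16 with 1 member at its bound), with the platelet chemokines Ppbp at −0.96 ± 0.23 and Pf4 at −0.56 ± 0.16. The erythroid and megakaryocyte list was not called (adjusted p = 0.0678), but was without untreated 1 (0.00229) and without anti-mu 1 (0.0218). Across the 27 lists camera called 10, 9 lower and 1 higher, and 0 were called with an estimated correlation or with fry. The estimated correlation alone does not account for this loss. For chemokines, cytokines and migration receptors it was −0.03, under the preset of 0.01, yet the unadjusted camera p rose from 6.7e-05 to 0.0527.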

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

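The authors' processed values with an offset and the crossed pairing were chosen after the data were seen, and the other alternatives were planned. Leaving out each sample was planned too, but keeping its tested probes was decided after a first run that filtered them again on 3 arrays, and both forms are given. Against 459 probes (55 higher) and 224 genes (31 higher), a normal-exponential correction on the signals alone gave 691 probes (147 higher) and 403 genes (97 higher). Without background correction there were 712 (154) and 412 (98), with median scaling 710 (21) and 386 (13), and with an intensity trend 762 (159) and 446 (103). The authors' processed values gave 31 probes (3 higher) and 6 genes (2 higher), and with an offset of 16 added to them 174 genes passed, 164 of them among the 224. Without a filter on dim probes 0 probes (0 higher) and 0 genes (0 higher) passed in limma, with 4830 probes at an unadjusted p under 0.05. More probes were tested there, and the prior degrees of freedom fell from 6.88 to 2.48. A 2-fold minimum left 249 probes (6 higher) and 111 genes (6 higher), and an adjusted p under 0.1 gave 834 (202) and 428 (105). Apart from these counts the cause of each difference was not tested.

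Leaving out each sample in turn gave 13 to 624 probes (0 to 115 higher), 0 to 338 genes (0 to 56 higher) and 7 to 13 gene lists, the lone sample being assumed to vary like the other group. The lowest counts came without anti-mu 1, with 13 probes, all lower, where 52 of the 52 named genes past the threshold lost their call. Some of their fold changes stayed close, as for Cd79b (−1.54 against −1.70) and Pou2af1 (−1.39 against −1.51). Others were smaller, as for Sbk1 (−1.41 against −1.84) and Trp53inp1 (−0.71 against −1.06), or larger, as for Tsc22d3 (−1.23 against −0.98). The genes were chosen on a fit with these same arrays, so similar fold changes and kept signs were largely given by that choice. Counts without untreated 1 or untreated 2 came from fits with infinite prior degrees of freedom, where all probes share 1 variance. They are not comparable with those without anti-mu 1 (5.53) or anti-mu 2 (5.97). Camera called 13 lists without anti-mu 1, with the pre-BCR list at an adjusted p of 5.4e-16 and a mean of −0.74 against −0.85. With the probes filtered again on the 3 arrays, the range was 13 to 539 probes (0 to 111 higher) and 0 to 309 genes (0 to 54 higher), again lowest without anti-mu 1, with 22 higher probes without anti-mu 2. Without untreated 2 there were 624 probes (115 higher) and 338 genes (56 higher), and without anti-mu 2 the higher probes numbered 34. Without anti-mu 2, 15 named genes lost their call, among them Vpreb1, Vpreb3, Ly6d and Btla, 4 did without untreated 1 and 4 without untreated 2. Of the 224 genes, 223 or 224 kept their sign in every setting that tested them all, with detection required on all 4 arrays 175 of the 175 tested did, and with probes filtered again all tested did except 1 of 196 without untreated 2. Camera called 10 lists, against 0 with an estimated correlation and 0 with fry.

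The labels do not pair the samples, and deviations of samples with the same number correlated at −0.22. With the replicate block, 838 probes (170 higher) and 441 genes (92 higher) passed, and the 224 genes were all among them. Camera called 11 lists there, with V(D)J recombination added (adjusted p = 0.0174). The prior degrees of freedom of the blocked fit were infinite, against 6.88 in the main fit, so the counts of the 2 fits are not directly comparable. With the pairing crossed, 607 probes (96 higher) and 330 genes (57 higher) passed. Camera called 11 lists with that pairing, with endoplasmic reticulum stress and the amino acid response added (adjusted p = 0.0492). A chip or slide block was not run, since no chip was named in the columns used. Signal over background limits the dim probes, where 13 members of the gene lists had only a bound.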

Other observations

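The marker subsets, and the tests of explanations made with them or with the intensity trend, were chosen after the results were seen, while the fits with that trend and without anti-mu 1 were planned. Among the myeloid markers, 5 neutrophil granule transcripts (Camp, Ngp, Ltf, S100a8 and S100a9) had a median log2 fold change of 0.82, with 0 past the threshold. Their median difference between anti-mu 1 and anti-mu 2 was −0.68, so the anti-mu arrays differed among themselves by a similar amount. Ngp had 0.83 ± 0.24 and Ltf 0.82 ± 0.23 (SE, n = 2 per group). The 5 macrophage transcripts Csf1r, Adgre1, C1qa, C1qb and C1qc lay between −0.66 and −0.45, also with 0 past the threshold. Among genes that rose outside the fixed lists, and chosen after their values were seen, were the cytokine gene Clcf1 (0.82), the vitamin D receptor Vdr (0.75), the ephrin receptor Epha2 (0.71) and the endocytic recycling gene Ehd1 (0.82).

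Of 16 B-restricted markers 12 fell, with a median of −1.19 over the 16 and of −1.33 over the 10 with an untreated level above 8 (log2) that served in the tests. If transcript levels within the cells stayed unchanged, a loss of all blood cells alike would lower macrophage and B-restricted markers equally. The macrophage median lay 0.76 above that of the B-restricted markers, more than the SDs of both sets together. On the same condition, a lower share of B-lineage cells as the only change in cell makeup would move all other cell types alike. The macrophage median minus the stromal median was −0.68. Both comparisons rest on 5 macrophage transcripts chosen after the results were seen, with 0 past the threshold. Changes within those cells were not measured, so neither comparison decides. A lower B-lineage share among other changes in makeup cannot be told apart from lower transcript levels within the cells: the spread of the markers' falls (SD 0.29) did not exceed permuted values (permutation p = 0.587) yet was above their typical standard error of 0.21. A response to pre-BCR engagement may also lower these transcripts, and it stays open as untested, because no sample measured the makeup of the cultures.

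The 31 genes that rose might reflect a higher share of stromal cells, which would raise stromal markers as well. The 27 stromal markers had a median of 0.11 (SD 0.25), so any common rise of stromal transcripts was small. The smallest rise among the 31 lay 0.59 above that median, but the threshold keeps smaller rises out of the 31 whatever their cause. That distance therefore does not decide the question. Noise of dim probes cannot be told apart from a rise: 87.1% of the 31 stayed past the threshold with an intensity-dependent prior variance, but that fit uses the same arrays and called 446 genes against 224, so it does not decide. Of the 31, 12 had a mean level above the median of all tested probes, and 5 were not detected in the untreated samples. Without anti-mu 1 0 of the 31 passed the threshold, with a median log2 fold change of 0.80 against 0.85 with all samples. A response to the antibody stays open as untested, since the arrays do not say which cells made these transcripts. A higher share of another cell type was not tested for the 31 either. The 5 neutrophil granule transcripts had a median log2 fold change of 0.82, with 0 past the threshold.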
